A study of Mus musculus with 24 samples.

How the data were processed

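Total RNA of 24 samples of ID8 mouse ovarian cancer cells was profiled by 3′ multiplexed RNA sequencing. Per the labels, 50000 cells per well were plated in 24-well plates in medium with 4% fetal calf serum 24 h before treatment with 10000 IU/ml IFN beta for 3 h, or were left untreated. RNA was purified on columns with DNase, and 20 ng were primed at the poly(A) tail with a sample index of 8 bp and a unique molecular identifier (UMI) of 10 bp, with a first read of 19 bp and a second read of 101 bp. The deposited counts are UMI counts per Ensembl gene that the authors made without normalization, with a column for each library. The submitters' processing notes name R 3.6.2 and 4.1.2, cutadapt 3.0, edgeR 3.36.0 and limma 3.50.0 and the builds GRCm38 and mm10 without saying which step each served, and the aligner is not given in the sources used here. Gene coordinates were taken from GENCODE M21 on GRCm38, to which 24538 of 24614 gene identifiers matched, and 8 of the tested genes did not match.

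Libraries were grouped by line and treatment as the labels give them, with 3 libraries in each of 8 groups. Library totals were 1972192 to 3097331 UMIs, with a median of 2512965, and mitochondrial genes held 1.15% to 1.82% of UMIs. Ratios with 1 to 3 UMIs in a group are given with an exact 95% counting interval, and ratios against 0 UMIs as lower bounds against a floor of 3 UMIs over the group. UMIs count molecules, and these intervals cover counting error alone. The replicate numbers were tested as a pairing of samples: the mean correlation of deviations from the group mean between libraries of the same number was 0.00928 (-0.0775 to 0.0830, 84 pairs) and between other libraries -0.00464 (-0.146 to 0.132). A total of 13 of 24 libraries lay closest to their own number, more than random numbering gives on average, so a weak pairing is not excluded. As the correlations were near 0, no pairing was used in the main fit, and a replicate block was among the other settings.

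Genes were kept by filterByExpr of edgeR with a minimum count of 10 and a minimum total of 15, which left 11698 genes holding 99.5% to 99.6% of UMIs. The 24 libraries were fitted together with edgeR 4.0.16 in R 4.3.3, with TMM scaling, robust dispersions and the quasi-likelihood F test on 8 group means. Contrasts were the response to IFN beta in each line, the differences of these responses (the clones' mean minus the controls' mean, EV minus WT, 2CD7 minus 1CF10) and the differences between untreated lines. The untreated contrast of clones with controls is the mean of 1CF10 minus EV and 2CD7 minus WT, which equals the mean of the clones minus the mean of the controls. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over the tested genes of a contrast, and the SE of a log2 fold change was its size divided by the square root of F. A gene common to both clones had to be called in the same direction in 1CF10 and 2CD7 against EV and against WT.

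The comparisons, the gene lists, the rule for naming genes and the other settings were written before the data were examined. Ifnar1, Ifnar2, Trp53 and Brca2 were always named. Of the genes called in the same direction in both controls, the 15 most raised and 8 most lowered by mean log2 fold change were named, and for each difference of responses up to 5 further genes per direction with the largest difference. At baseline, the 10 genes per direction common to both clones with the largest minimum change over the 4 contrasts were named, and for EV against WT and each clone against EV up to 5 per direction with the largest change. These genes had an average log2 CPM of at least 1 where the rule ranked by size, and predicted genes were skipped. Of each list, up to 4 called members with the largest change could be named, with exceptions. Lists of antiviral effectors, GTPases, nucleic acid sensors, antigen processing, interferon signalling, checkpoint ligands, chemokines and cytokines, cell death, immediate early, cell cycle, cholesterol synthesis, unfolded protein response, mesothelial, matrix, hypoxia and glycolysis, homologous recombination, mitochondrial mRNA, NF-kB target, p53 target and ribosomal protein genes were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. A list needed at least 5 tested members, so lists of leukocyte and endothelial markers were left out of this test.

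The other settings were RLE size factors in edgeR, the Wald test of DESeq2 1.42.0, limma-voom, no filter on low counts, a filter with a minimum count of 30, the replicate number as a block, all libraries thinned to 1972192 UMIs, a fit of the compared groups alone, leaving out each replicate in turn and, for lists, the estimated correlation. When a group is left with fewer libraries, the edgeR spread is pooled over groups, which assumes that its libraries vary like the others. Chromosome medians used genes with an average log2 CPM above 4 and 1000 random gene sets, and bootstrap intervals used 2000 draws of genes. The procedure was tested on simulated data, drawn from the real means, library sizes and dispersions. In treated 1CF10, 50 genes each were changed 1.25-, 1.5-, 2- and 4-fold, picked at random among genes with an average log2 CPM above 2. The procedure called 10%, 50%, 76% and 100% of them in the right direction, and 9 unchanged genes. For changes made in the controls alone, the difference of responses called 6%, 46%, 78% and 100%, with 7 unchanged genes. Of genes made 2-fold lower in both clones, 64% were called in all 4 contrasts with 0 others, and a list raised by a log2 change of 0.5 was measured at 0.49. Of 200 changed genes, edgeR and limma-voom called 118 each and DESeq2 105.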

Results

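Gene expression was measured in ID8 cells, a mouse ovarian cancer line that the labels describe as a knockout of the tumour suppressor gene Trp53 and the DNA repair gene Brca2. Untransfected cells (WT), cells given an empty vector (EV) and 2 clones with a CRISPR knockout of Ifnar1, named 1CF10 and 2CD7, were compared. Ifnar1 encodes a chain of the receptor through which cells sense type I interferons. Each line was sampled untreated and after 3 h of recombinant mouse interferon beta (IFN beta) at 10000 IU/ml, which gave 8 groups of 3 libraries. The 3 libraries of a group were technical replicates treated on the same date, so every p-value measures technical spread alone, and each clone stands for itself. A total of 24 libraries held 1972192 to 3097331 unique molecular identifiers (UMIs), with 15685 to 16951 genes detected in each. The untreated groups averaged 2372100 ± 482580 (SD, n = 3) UMIs in WT, 2471600 ± 17054 in EV, 2735300 ± 397770 in 1CF10 and 2609400 ± 122460 in 2CD7. After IFN beta the same averages were 2654800 ± 210890, 2512700 ± 211350, 2673600 ± 293570 and 2445700 ± 330070. Of the 24614 genes in the table, 11698 were tested. Log2 fold changes and log2 differences are given ± SE, and CPM (counts scaled to the library total) ± SD with n = 3.

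Ifnar1 transcripts were still counted in both clones, and the difference of either untreated clone from either untreated control did not pass the test. The untreated libraries averaged 11.5 ± 4.5 CPM (SD, n = 3) in WT, 11.9 ± 1 in EV, 8.71 ± 2.5 in 1CF10 and 7.37 ± 2.7 in 2CD7. With IFN beta these averages were 15.2 ± 1.7, 11.4 ± 1.9, 11.1 ± 1.2 and 7.52 ± 0.96. Each treated 2CD7 library (6.53 to 8.45 CPM) lay below each treated control library (9.24 to 17.1 CPM), while treated 1CF10 overlapped with treated EV. Treated clones were not tested against treated controls. Against untreated EV the log2 difference of Ifnar1 was -0.46 ± 0.25 in 1CF10 and -0.68 ± 0.27 in 2CD7, with edgeR adjusted p = 0.292 and 0.102. Against untreated WT it was -0.37 ± 0.26 and -0.59 ± 0.27, with edgeR adjusted p = 0.353 and 0.255. The libraries counted tags primed at the poly(A) tail, and Ifnar1 (GRCm38 chromosome 16, 91485238 to 91507441, plus strand) ends in a long exon 11 from 91505055 to 91507441. A tag in that exon can come from an edited transcript, so these counts do not check the knockout, and with 11 to 44 UMIs per library a modest loss may have been missed. Over both clones and both controls the untreated difference of Ifnar1 was -0.53 ± 0.19, with edgeR adjusted p = 0.0713, and -0.62 with edgeR adjusted p = 0.0492 without untreated 2CD7 library 3, the lowest of the alternatives' adjusted p, which ran up to 0.435. Transcripts of Trp53 and Brca2 were counted in every library too, at 8.82 to 20.3 and 10.98 to 34.6 CPM, and their tags do not check those knockouts either. Ifnar2, the partner chain of the receptor, and Trp53 passed the edgeR test in no comparison of untreated lines or of treatment. Brca2 counts were lower after IFN beta in WT at -0.67 ± 0.19, higher in untreated EV than in WT at 0.54 ± 0.17, higher in untreated 1CF10 than in WT at 0.51 ± 0.17 and lower in untreated 2CD7 than in EV at -0.73 ± 0.17, with edgeR adjusted p = 0.0190, 0.0181, 0.0194 and 0.00166.

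The first question was which genes the controls change when they meet IFN beta. Antiviral genes were among those that rose: Rsad2, which encodes the antiviral enzyme viperin, rose by a log2 fold change of 7.37 ± 0.21 in WT and 6.54 ± 0.20 in EV, and Ifit1, whose product binds foreign RNA caps, rose by 6.64 ± 0.27 and 6.23 ± 0.26. Cxcl10, a chemokine that attracts T cells, rose by 6.21 ± 0.25 in WT and 6.49 ± 0.25 in EV. Cmpk2, a mitochondrial nucleotide kinase, rose by 6.73 ± 0.21 and 5.34 ± 0.19, and Usp18, a protease that restrains interferon signalling, by 6.26 ± 0.30 and 5.45 ± 0.29. Among the interferon-inducible GTPases, Igtp rose by 6.21 ± 0.25 and 5.43 ± 0.25, Tgtp2 by 5.79 ± 0.23 and 6.50 ± 0.31, and Gbp7 by 5.29 ± 0.28 and 5.96 ± 0.31. Iigp1, another of these GTPases, rose by 7.49 ± 0.32 in WT and 446-fold (95% counting interval 123 to 3692) in EV, where the untreated libraries held 2 UMIs. Mx1, an antiviral GTPase, rose by 6.02 ± 0.37 in WT and 65.1-fold (95% counting interval 22 to 319) in EV. Ifit1bl1, Ifit3 and Ifit3b rose by 7.33, 5.77 and 5.67 in WT and by 6.46, 6.0 and 6.18 in EV, and Ifi206 rose 72.5-fold (95% counting interval 24.5 to 354) in WT and 171-fold (95% counting interval 30.3 to 6796) in EV. Olfr56, which overlaps Tgtp2 in the annotation, was at least 26.4-fold higher in WT and at least 13.8-fold in EV against a floor of 3 UMIs over the untreated group. The Ifit, Ifi206, Tgtp and Gbp genes have near-identical copies, so their single values are uncertain. The largest edgeR adjusted p among these 15 genes was 9.56e-08.

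Fewer genes fell, and by less. Among the genes called in both controls, Sox11, which encodes a developmental transcription factor, fell most, with a log2 fold change of -2.00 ± 0.49 in WT and -1.21 ± 0.35 in EV. Trib2, a pseudokinase gene, changed by -1.43 ± 0.15 and -1.12 ± 0.16, and Edn1, which encodes the peptide endothelin-1, by -0.96 ± 0.24 and -0.54 ± 0.14. Herpud1, of the degradation pathway at the endoplasmic reticulum, changed by -0.67 ± 0.14 and -0.84 ± 0.15, and the kinase gene Sgk1 by -0.89 ± 0.08 and -0.56 ± 0.08. Mgat3, Mllt11 and Chst1 were lower by -0.61, -0.89 and -0.84 in WT and by -1.19, -0.91 and -0.82 in EV. The largest edgeR adjusted p among these 8 genes was 0.0455. In WT, 586 genes rose and 215 fell, of which 287 and 15 changed at least 2-fold, and in EV 467 rose and 129 fell, with 259 and 11 at least 2-fold. Of these, 398 rose in both lines, where independent lists would share 23.4, and 42 fell in both against 2.37, and no gene moved in opposite directions. A total of 228 of the 398 rose at least 2-fold in both lines. Across the 957 genes called in either line, the log2 fold changes of EV and WT correlated with r = 0.941 and 91.2% had the same sign, although genes are not independent replicates. The number of falling genes was smaller whichever library was left out, at 120 to 160 in WT and 75 to 113 in EV. Changes beyond 1.5 times were as follows. In WT it was 120 without untreated library 2, 131 without untreated library 3, 125 without treated library 2 and 127 without treated library 3. In EV it was 75 without untreated library 1, 81 without treated library 1, 83 without treated library 2 and 75 without treated library 3. DESeq2 called 119 falling genes in WT and 66 in EV.

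Gene groups fixed beforehand moved with these genes. Of 57 tested antiviral effectors, 56 rose in WT and 54 in EV, the same counts as adjusted over the list alone, with median log2 fold changes of 3.24 and 2.68. Ifitm2 passed the test in neither line, and Ifi27 and Ifi27l2a did not pass it in EV. All 19 guanylate-binding and immunity-related GTPases rose in EV and 18 in WT (19 adjusted over the list alone), with medians of 4.72 and 5.29, or 4.68 and 5.04 with genes absent from untreated libraries set at their bound. Of 17 nucleic acid sensors, 14 rose in each line (15 in WT and 14 in EV adjusted over the list alone). Among them were Ifi203 (5.46 ± 0.17 and 5.01 ± 0.17), the RNA sensor gene Tlr3 (4.40 ± 0.32 and 5.27 ± 0.42) and Zbp1, a sensor of Z-form nucleic acids (4.88 ± 0.36 and 4.95 ± 0.44). Antigen presentation rose as well: 18 of 23 class I and antigen processing genes in WT and 17 in EV (20 and 17 adjusted over the list alone). The peptide transporter gene Tap1 rose by 5.25 ± 0.30 and 4.34 ± 0.28 and the immunoproteasome gene Psmb9 by 4.24 ± 0.32 and 4.77 ± 0.42, while Psmb8 rose by 4.07 ± 0.43 in WT and 52.6-fold (95% counting interval 9.04 to 2118) in EV. Of 28 interferon signalling genes and regulators, 16 rose in WT and 15 in EV (16 and 17 adjusted over the list alone). They were led by Usp18 and by Socs1, a feedback inhibitor (4.93 ± 0.22 and 4.56 ± 0.21), with the transcription factor gene Irf7 at 4.09 ± 0.29 and 3.25 ± 0.28. Cd274, which encodes the checkpoint ligand PD-L1, rose by 4.36 ± 0.27 and 5.07 ± 0.27, and Lgals9, Cd47 and Nectin2 completed the 4 of 6 checkpoint ligands that rose in each line (5 in WT and 4 in EV adjusted over the list alone). These 6 groups were called in both lines by camera (limma), with adjusted p at most 5.18e-17 with the preset correlation and 1.65e-05 with an estimated correlation.

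Secreted and death-related genes rose in part. Among 21 chemokines and cytokines, 9 rose and 1 fell in WT, and 7 rose and 1 fell in EV (9 and 1, and 8 and 2, adjusted over the list alone). Tnfsf10, the death ligand TRAIL, was at least 14.7-fold higher in WT and at least 7.76-fold in EV. The chemokine gene Ccl8 rose 50.7-fold (95% counting interval 17.0 to 248) in WT and by a log2 fold change of 2.02 ± 0.48 in EV. Il15, a growth factor for lymphocytes, rose by 3.12 ± 0.34 and 3.01 ± 0.40. Cxcl12 fell in both lines, with -0.35 ± 0.09 and -0.59 ± 0.08. Of 33 cell death genes, 13 rose and 3 fell in WT, and 12 rose and 0 fell in EV (15 and 3, and 13 and 2, adjusted over the list alone). The largest changes beside Tnfsf10 were those of Daxx (3.27 ± 0.11 and 2.98 ± 0.11), the inflammatory caspase gene Casp4 (2.51 ± 0.18 and 2.02 ± 0.18) and the death receptor gene Fas (2.24 ± 0.62 and 2.57 ± 0.55). camera (limma) called both groups, with adjusted p at most 1.49e-05 and, with an estimated correlation, 0.000508. Of 23 immediate early genes, 9 rose in WT and 7 in EV (11 and 9 adjusted over the list alone, with 3 and 1 falling), led by Zfp36, which encodes an mRNA decay factor (1.49 ± 0.24 and 1.44 ± 0.25). For this group the camera (limma) adjusted p = 0.000305 and 0.00806 became 0.0831 and 0.204 with an estimated correlation. In WT, 7 of 44 cell cycle genes fell and 1 rose (12 and 1 adjusted over the list alone), among them Rrm2 (-0.51 ± 0.09) and the cyclin gene Ccnd1 (-0.42 ± 0.07). The group had camera (limma) adjusted p = 0.000963, or 0.0132 with an estimated correlation. In EV 1 rose and 1 fell, and the adjusted p from camera was 0.0577. Of 8 mesothelial and surface epithelial markers, the keratin genes Krt18 (0.92 ± 0.06) and Krt8 (0.45 ± 0.10) rose in WT (3 adjusted over the list alone), and 2 rose in EV (2 adjusted over the list alone). This group had camera (limma) adjusted p = 0.00699 in WT and 0.229 in EV, and 0.0354 in WT with an estimated correlation.

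The remaining groups moved little. The cholesterol synthesis group, which also holds fatty acid genes such as Fasn and Scd2, was called lower in WT. There Fasn (-0.46 ± 0.10) and Hmgcs1 (-0.40 ± 0.11) were the 2 of 29 that fell (6 adjusted over the list alone). The camera (limma) adjusted p was 0.0191, or 0.150 with an estimated correlation. In EV 2 of 29 fell too (4 adjusted over the list alone), with camera (limma) adjusted p = 0.0938. Unfolded protein response genes were called lower in EV, where 3 of 26 fell (4 adjusted over the list alone), led by Herpud1 (-0.84 ± 0.15) and Ddit3, a stress transcription factor gene (-0.74 ± 0.22), with camera (limma) adjusted p = 0.00390, or 0.177 with an estimated correlation, and 0.0774 in WT. Homologous recombination, hypoxia and glycolysis, mesenchymal and matrix, mitochondrial mRNA, NF-kB target, p53 target and ribosomal protein groups were called in neither line, with camera (limma) adjusted p of at least 0.0774. Single members did pass the edgeR test, such as Fbn1, a matrix gene (1.66 ± 0.52 and 2.07 ± 0.62), and Hk2, a glycolysis gene (1.07 ± 0.10 and 0.92 ± 0.09). Markers of leukocytes and of endothelial cells, which would mark other cell types, were rarely counted: 1 of 32 and 2 of 16 members were abundant enough to test.

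**Figure D1:**
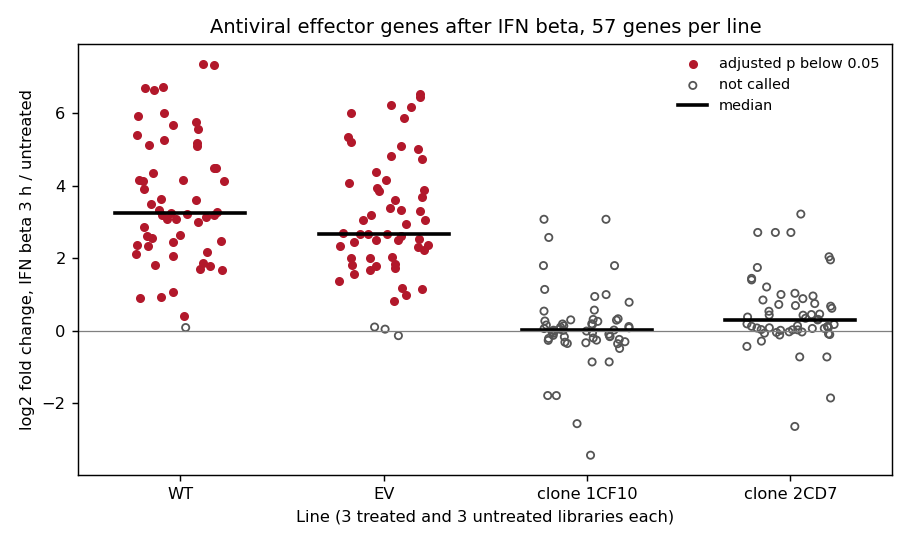
Fitted log2 fold changes after 3 h of IFN beta for the 57 tested antiviral effectors in each line, with filled points for edgeR adjusted p below 0.05 and bars for medians. The medians are 3.24 in WT and 2.68 in EV, against 0.02 in 1CF10 and 0.30 in 2CD7, where no gene passed the test and wide values come from genes with few UMIs.

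**Figure D2:**
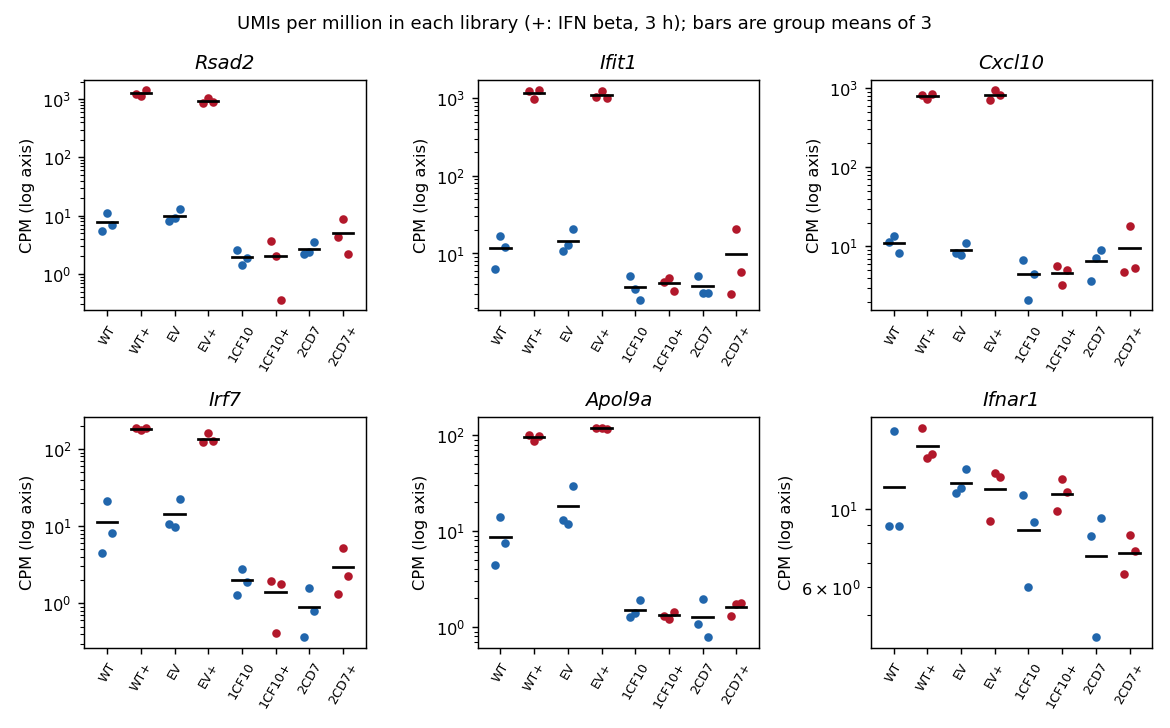
CPM of 6 genes in each library on log axes, with blue points for untreated and red points for IFN beta treated libraries and bars for the means of 3. Rsad2, Ifit1, Cxcl10, Irf7 and Apol9a are higher in all 6 treated control libraries than in any other library.

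The second question was whether the Ifnar1 clones respond. In neither clone did any gene pass the test, and the strongly raised genes of the controls given here were counted at low levels with and without IFN beta. Rsad2 averaged 1.95 ± 0.57 CPM (SD, n = 3) in untreated and 2 ± 1.6 CPM in treated 1CF10, and 2.69 ± 0.74 and 5.13 ± 3.4 CPM in 2CD7. The controls averaged 7.8 ± 3 and 1260 ± 150 CPM in WT and 10 ± 2.7 and 934 ± 110 CPM in EV. The log2 fold change of Ifit1 was 0.19 ± 0.79 in 1CF10 and 1.45 ± 0.65 in 2CD7, and that of Cxcl10 was 0.13 ± 0.64 and 0.63 ± 0.51. The 398 genes raised in both controls had median log2 fold changes of 1.41 in WT, 1.23 in EV, 0.0033 in 1CF10 and 0.066 in 2CD7. The 42 lowered genes had medians of -0.52, -0.47, 0.012 and 0.0098. edgeR called 0 genes in 1CF10, with 485 at an unadjusted p below 0.05, and DESeq2 and limma-voom called 0 with 223 and 505. In 2CD7, edgeR called 0 genes with 510 at an unadjusted p below 0.05, and DESeq2 and limma-voom called 0 with 249 and 515, while 1 gene was called lower by edgeR without treated library 1. On simulated data, this test of 1CF10 recovered 50% of genes changed 1.5-fold, 76% of those changed 2-fold and 100% of those changed 4-fold, so smaller changes could have been missed. The simulation gave a gene the same spread in all groups. Treated 1CF10 library 3 differed more from its replicates, with a chi-square per gene of 4.74 and 3.68, so these shares may be too high for the real libraries. Genes with few UMIs in the clones, such as Rsad2, were not simulated apart, so larger changes in them could have been missed too.

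Gene groups moved little in the clones, and no member of any group passed the test over all genes. Adjusted over the list alone, 2 of 23 immediate early genes were lower in 2CD7, Myc (-0.40 ± 0.12) and Fosl1 (-0.48 ± 0.14), both named after their values were seen, with an edgeR adjusted p over all genes of 0.956 for both, and no other group had such a call in either clone. In 2CD7 the antiviral effectors had a median log2 fold change of 0.30, or 0.19 with genes at 0 set at their bound, and the GTPases had 0.64 or 0.50. Both groups had camera (limma) adjusted p = 0.000915, which became 0.736 and 0.654 with an estimated correlation. The antiviral median rested on treated library 2, and was 0 without it. That library held 736 CPM of the 123 genes raised at least 4-fold in both controls, against 510.1 and 500.1 CPM in the other treated 2CD7 libraries, 460.3 to 487.2 CPM in untreated 2CD7 and 12468 to 17410 CPM in the treated controls. Ribosomal protein and immediate early genes were called lower and mitochondrial mRNAs higher in 2CD7, with medians of -0.07, -0.08 and 0.11 and camera (limma) adjusted p = 2.36e-06, 0.000915 and 0.0463, or 0.654 for each with an estimated correlation. In 1CF10 the antiviral median was 0.02, and ribosomal protein and immediate early genes were called lower with medians of -0.06 and -0.07 and camera (limma) adjusted p = 2.27e-05 and 0.0339, or 0.591 for both with an estimated correlation.

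A direct test of the difference between the clones' and the controls' responses found 430 genes with a lower and 183 with a higher response in the clones. Socs1 had a response lower by a log2 difference of -5.13 ± 0.34, the RNA-binding antiviral gene Ifit2 by -5.39 ± 0.66 and the GTPase gene Gbp2 by -5.13 ± 0.33, while Rsad2 had -6.40 ± 0.70, Ifit1 -5.62 ± 0.71 and Cxcl10 -5.97 ± 0.56. Mx2 and Ifi44 were also called, after rising by 5.56 ± 0.32 and 5.10 ± 0.33 in WT and 5.02 ± 0.33 and 3.89 ± 0.29 in EV, but with 0 to 4 UMIs in treated clones the size of their difference is open. Among genes with a higher response in the clones, Mycn, an oncogenic transcription factor gene, differed by 2.01 ± 0.60 and fell 8.89-fold (95% counting interval 2.13 to 79.0) in EV, and Slc40a1, the iron exporter gene, differed by 1.45 ± 0.39. Pxdn differed by 1.62 ± 0.47, the interferon lambda receptor gene Ifnlr1 by 1.34 ± 0.42 and Sord by 1.29 ± 0.33. The largest edgeR adjusted p among these named genes was 0.0461. Of the 430 genes, 401 were raised in WT or EV and 332 in both, and of the 183, 110 were lowered in WT or EV and 41 in both, out of the 42 that both controls lowered. The difference holds the same control responses, and the clones changed little, so this overlap is largely built in and is no independent support. By group, 40 of 57 antiviral effectors had a lower response (44 adjusted over the list alone), as did 13 of 19 GTPases (14), 11 of 17 sensors (15), and 15 of 23 class I genes (17). So did 13 of 28 signalling genes (14), 4 of 6 checkpoint ligands (4) and 9 of 23 immediate early genes (13, with 2 higher). camera (limma) gave these 7 groups adjusted p at most 7.57e-09, or 0.00874 with an estimated correlation. Genes of the cholesterol synthesis group had a higher response, with 5 of 29 called, among them the fatty acid gene Scd2 (0.64 ± 0.14) and Hmgcs1 (0.45 ± 0.12). The camera (limma) adjusted p was 0.000997, or 0.0445 with an estimated correlation. Chemokines and cytokines (7 of 21 lower and 1 higher, 7 and 2 adjusted over the list alone), cell death genes (8 of 33 lower and 1 higher, 14 and 3), mesothelial markers (2 of 8 lower) and cell cycle genes (3 of 44 higher and 1 lower) were called with camera (limma) adjusted p at most 0.0111, or 0.0457 with an estimated correlation. Ribosomal protein genes (0 called) and unfolded protein response genes (2 of 26 higher) had camera (limma) adjusted p = 0.00253 and 0.00216, but 0.488 and 0.122 with an estimated correlation. DESeq2 called 89 genes with a higher and 389 with a lower response.

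The responses of EV and WT differed in few genes, and between the clones no gene passed the test. Rrm2, a ribonucleotide reductase subunit gene, fell in WT (-0.51 ± 0.09) but not in EV (0.08 ± 0.09), a log2 difference of 0.59 ± 0.12. Ssr1, of the protein translocation machinery, went from -0.34 ± 0.08 in WT to 0.20 ± 0.08 in EV, a difference of 0.54 ± 0.11. Nrn1, which encodes neuritin, differed by 0.56 ± 0.12. The predicted genes 9930111J21Rik2 and Gm6475, named after their values were seen, had a lower response in EV by -0.88 ± 0.18 and -1.43 ± 0.26. The edgeR adjusted p of these 5 genes were 0.0473, 0.0299, 0.0473, 0.0299 and 0.00743. The responses of antiviral effectors in EV and WT had a median difference of -0.55. Over all genes 0 of 57 were called, and 10 were called lower adjusted over the list alone. For this group the camera (limma) adjusted p was 3.18e-09, but 0.400 with an estimated correlation. Cell cycle, immediate early, mesothelial, class I and sensor genes were called as well, with camera (limma) adjusted p from 0.0133 to 0.0432, but from 0.308 with an estimated correlation. These 3 higher and 2 lower calls were unsteady: DESeq2 gave 0 and 1 and limma-voom 1 and 1. Leaving out 1 library gave 0 higher calls without WT untreated library 3, WT treated library 2 or 3, EV untreated library 1 or 2, or any of the 3 treated EV libraries, 1 without WT treated library 1 and 12 without EV untreated library 3. Lower calls numbered 21 without WT untreated library 2, 4 without WT treated library 2, 7 without EV untreated library 3, 1 without WT treated library 1 or 3 or EV treated library 1 or 3, and 0 without EV untreated library 1. Between the responses of 2CD7 and 1CF10, edgeR called 0 genes, with 474 at an unadjusted p below 0.05, and DESeq2 and limma-voom called 0 with 213 and 477. GTPases and mitochondrial mRNAs differed there with camera (limma) adjusted p = 0.00640 and 0.0195, but 0.690 for both with an estimated correlation.

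The third question was how the clones differ from the controls without added IFN beta. Interferon-stimulated genes were lower in both untreated clones: Irf7, a transcription factor that amplifies interferon signalling, differed by log2 -2.79, -2.38, -3.93 and -3.52 for 1CF10 against EV, 1CF10 against WT, 2CD7 against EV and 2CD7 against WT. In that order, Irf9, another interferon-related transcription factor gene, differed by -2.26, -2.07, -2.86 and -2.66, the chaperone gene Rtp4 by -3.13, -2.48, -3.91 and -3.25 and Apol9a by -3.50, -2.41, -3.78 and -2.69. Ifi27l2a differed by -2.50, -1.82, -3.24 and -2.55 and Apol9b by -3.78, -2.85, -2.92 and -1.98. Gbp3 was lower in 1CF10 by -3.00 ± 0.93 and -2.99 ± 0.94, and in 2CD7, with 1 UMI, 40.2-fold (95% counting interval 6.80 to 1631) and 39.7-fold (95% counting interval 6.69 to 1612) lower. Trim12c had 0 UMIs in both untreated clones and was, in the same order, at least 3.77-fold, at least 5.49-fold, at least 3.53-fold and at least 5.15-fold lower against a floor of 3 UMIs over the group. Apol9a and Apol9b, Gbp3 and Trim12c have near copies and are uncertain one by one. Ggh, a folate hydrolase gene, and Cacna2d2, a calcium channel subunit gene, were lower by -2.17, -2.69, -2.90 and -3.42 and by -2.02, -2.35, -2.17 and -2.50, although neither rose with IFN beta. SEs of the differences of Irf7, Irf9, Rtp4, Apol9a, Ifi27l2a, Apol9b, Ggh and Cacna2d2 ran from 0.26 to 0.79, and with Gbp3 and Trim12c included the edgeR adjusted p was at most 0.0463. Id2, a transcriptional inhibitor gene, was higher by 0.44, 0.45, 0.48 and 0.49, and the mitochondrial tRNA gene mt-Tm by 0.55, 0.45, 0.53 and 0.43. Jmjd6, Rassf1 and Upk1b were higher too, by at least 0.32, 0.30 and 0.23 in each contrast, with edgeR adjusted p at most 0.0380 for the 5 higher genes.

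In all, 28 genes were lower and 5 higher in both clones against both controls. Of the 28 lower genes, 18 were among the 398 that IFN beta raised in both controls, where 0.953 would be shared by independent lists (Fisher's exact test, one-sided p = 2.46e-20), and of the 5 higher genes 0 were. Fisher's test takes genes as independent, which genes that respond together are not, and its p does not cover spread between lines. The clones share their controls, so a difference of a control alone can make their lists overlap. In 20 simulations with all untreated lines alike, the log2 fold changes of the 2 clones against EV had a mean correlation of 0.521. Even so, 0 genes were called in the same direction in both clones against EV, or in all 4 contrasts. Controls that differ from each other, as EV and WT do, were not simulated. Against EV, 217 genes were lower in both clones, where independent lists would share 38.5, and 99 were higher against 16.8, and against WT 159 were lower against 26.6 and 93 higher against 13.9. With a different control for each clone, 53 genes were lower in 1CF10 against EV and 2CD7 against WT, where independent lists share 16.3, and 71 in the opposite pairing, against 62.7. For higher genes these values were 20 against 6.12 and 11 against 38.3, so the overlap was smaller with separate controls. The 28 lower genes became 13 without untreated WT library 2 and 16 without untreated 2CD7 library 1, and the 5 higher genes became 3 without untreated WT library 3, EV library 1, 1CF10 library 2 or 2CD7 library 1.

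**Figure D3:**
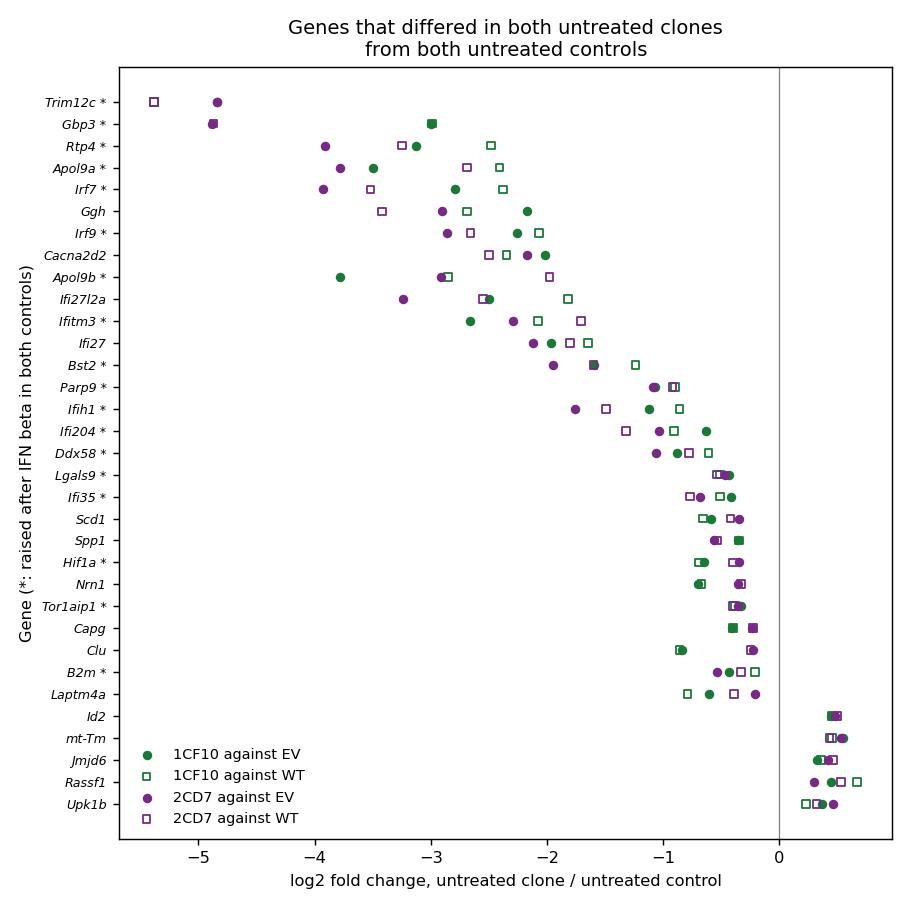
Fitted log2 fold changes of the 33 genes called in the same direction in all 4 comparisons of an untreated clone with an untreated control, with a point per comparison and an asterisk for genes raised by IFN beta in both controls. The 28 lower genes hold all 18 marked ones, and the values of Trim12c are fitted against 0 UMIs and are no measured size.

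Gene groups were also compared between the mean of the untreated clones and the mean of the untreated controls. Antiviral effectors were lower, with 33 of 57 called (43 adjusted over the list alone, with 1 higher) and a median log2 difference of -1.14. Untreated WT library 2 and EV library 3 held 1267 and 1145 CPM of the 123 genes raised at least 4-fold in both controls, against 666 and 826 CPM in the other WT and 818 and 833 CPM in the other EV libraries. Without these 2 libraries and treated 2CD7 library 2, left out after the data were seen, the median was -0.83. GTPases (7 of 19 called, 9 adjusted over the list alone), nucleic acid sensors (7 of 17, and 7) and signalling genes (6 of 28 lower and 1 higher, and 8 and 1) were lower too, although signalling genes were not called as a group in either clone against EV (camera (limma) adjusted p = 0.0927 in 1CF10 and 0.0668 in 2CD7). Of these, the viral RNA sensor gene Ifih1 stood at -1.31 ± 0.20, while the phosphatase gene Ptpn6 was higher by 1.09 ± 0.25. Cholesterol synthesis genes were lower in 18 of 29 cases and higher in 1 (23 and 1 adjusted over the list alone), with a median of -0.36, led by Hmgcs1 (-0.71 ± 0.08), Mvd (-0.62 ± 0.12) and Nsdhl (-0.58 ± 0.10). By clone, 19 and 20 of these genes were lower in 1CF10 against EV and WT, with medians of -0.51 and -0.54, but 5 and 4 in 2CD7, with medians of -0.04 and -0.17. Immediate early genes were higher in 7 of 23 cases (8 adjusted over the list alone), led by Fosl1, of the AP-1 family (0.64 ± 0.10), and cell cycle genes in 6 of 44 with 1 lower (9 and 1), led by Ccnd1 (0.36 ± 0.05). Fosl1 was itself higher in EV than in WT, and it was lower in 2CD7 than in EV. The clones differed here: 7 and 16 immediate early genes were higher in 1CF10 against EV and WT, while in 2CD7 9 were lower against EV and 2 higher against WT, and of the cell cycle genes 6 and 18 were higher in 1CF10 with 2 and 1 lower, while in 2CD7 2 were lower against EV and 2 higher against WT. Among NF-kB targets, Ccl2 was higher (0.88 ± 0.07) and Tnfaip2 lower (-0.22 ± 0.06). Ccl2 was itself lower in EV than in WT, and it did not pass the test in 1CF10 against WT. These 8 groups had camera (limma) adjusted p at most 0.00393, and at most 0.0397 with an estimated correlation. Mitochondrial mRNAs (4 of 13 lower), unfolded protein response genes (6 of 26 lower), class I genes (3 of 23 lower, among them B2m at -0.38 ± 0.05) and glycolysis genes (4 of 27 lower and 1 higher) were called with camera (limma) adjusted p = 0.000480, 0.000102, 0.0167 and 0.0208, but not with an estimated correlation (0.156, 0.0727, 0.311 and 0.0814). In 2CD7 against EV, these 4 groups, the NF-kB targets and the cholesterol synthesis genes were not called, with camera (limma) adjusted p at least 0.308. Against WT, cholesterol synthesis genes, class I genes and mitochondrial mRNAs were called lower in 2CD7, with camera (limma) adjusted p = 0.000262, 0.000677 and 0.0485, or 0.0424, 0.161 and 0.540 with an estimated correlation, and the other 3 groups were not (at least 0.580).

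The controls themselves differed without treatment, in 814 genes higher and 835 lower in EV than in WT. Xist, the RNA that silences an X chromosome, had 75 UMIs in untreated WT and 0 in EV, at least 26.0-fold lower. The untreated clones were like EV here, with 2 Xist UMIs in 1CF10 and 0 in 2CD7. Tmem184a and Sema5a were at least 9.72-fold and at least 8.33-fold lower in EV, Kctd14 was lower by -4.63 ± 0.35 on the log2 scale, and Raet1e, a stress ligand gene, was 21.4-fold (95% counting interval 5.55 to 182) lower. Col5a1, a fibrillar collagen gene, was higher in EV by 3.83 ± 0.56, Myh15 by 3.58 ± 0.56 and Havcr2, the immune receptor gene TIM-3, by 3.32 ± 0.57, while Igsf11 was 26.9-fold (95% counting interval 4.44 to 1099) and Ifi27l2b 13.4-fold (95% counting interval 3.39 to 116) higher. Immediate early genes were higher in EV in 12 of 23 cases (16 adjusted over the list alone), led by Fosl1 (2.10 ± 0.14), Gadd45g (1.32 ± 0.16) and the YAP target gene Ccn2 (1.28 ± 0.17). Higher too were 12 of 44 cell cycle genes with 1 lower (19 and 2). Mesothelial markers were lower in 4 of 8 cases and higher in 1 (4 and 1 adjusted over the list alone), led by the uroplakin gene Upk3b (-2.70 ± 0.38) and the transcription factor gene Wt1 (-0.74 ± 0.08). These 3 groups had camera (limma) adjusted p at most 1.50e-05, or 0.00567 with an estimated correlation. Matrix genes were called higher (14 of 26, with 4 lower), antiviral effectors higher (7 of 57, with 2 lower) and class I genes lower (6 of 23, with 1 higher), with camera (limma) adjusted p = 0.0122, 0.0290 and 0.0327, but 0.141, 0.718 and 0.687 with an estimated correlation. The largest edgeR adjusted p among the genes named here was 0.000249. The 835 lower genes became 551 without untreated WT library 3.

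Clone 1CF10 differed from EV in 421 higher and 791 lower genes when untreated. With 1 UMI each in EV, Glipr2 was 82.3-fold (95% counting interval 14.4 to 3286) higher, Rnf144b 61.1-fold (95% counting interval 10.6 to 2447), Dync1i1 39.8-fold (95% counting interval 6.79 to 1608), Rgs4, a regulator of G-protein signalling, 37.2-fold (95% counting interval 6.32 to 1503) and Rab38 33.6-fold (95% counting interval 5.68 to 1363). Fam149a, the antiviral helicase gene Ddx60 and the chromatin remodeller gene Smarca1 had 0 UMIs in 1CF10, at least 21.1-fold, at least 5.65-fold and at least 5.27-fold lower. Pimreg was lower by -5.22 ± 0.41 and Oas1g, of the antiviral 2-5A synthetases and with near copies, by -5.22 ± 0.61. Of 57 antiviral effectors 28 were lower and 1 higher (35 and 1 adjusted over the list alone), with a median of -1.43, or -1.27 with genes at 0 set at their bound, and camera (limma) adjusted p = 2.54e-22, or 0.0586 with an estimated correlation. Against WT 18 were lower (24 adjusted over the list alone), with a median of -0.99, or -0.86 at the bound, and camera (limma) adjusted p = 7.10e-08, or 0.234 with an estimated correlation. Cholesterol synthesis genes were lower in 19 of 29 cases (24 adjusted over the list alone, with 1 higher), led by Mvd (-1.0 ± 0.18) and Nsdhl (-0.85 ± 0.14), and unfolded protein response genes in 6 of 26 (8), led by Chac1 (-1.27 ± 0.19). Matrix genes were higher in 8 of 26 cases and lower in 3 (the same adjusted over the list alone), led by Col1a1 (1.97 ± 0.13), Timp3 (1.91 ± 0.17), Lox (1.84 ± 0.20) and Dcn (1.64 ± 0.24). NF-kB targets were higher in 5 of 22 cases with 1 lower (8 and 1), led by Traf1 (1.56 ± 0.51) and Ccl2 (1.44 ± 0.11). These last 4 groups had camera (limma) adjusted p at most 0.00483, or 0.0438 with an estimated correlation. Of the genes named here, Glipr2, Rgs4, Rab38, Pimreg, Oas1g, Chac1, Col1a1, Lox, Dcn and Ccl2 had differed between EV and WT in the opposite direction, and in 1CF10 against WT only Glipr2, Pimreg and Col1a1 of these 10 passed the test (edgeR adjusted p of the other 7 at least 0.234). The largest edgeR adjusted p among the genes named here was 0.0351, and DESeq2 called 279 higher and 593 lower genes. GTPases, glycolysis genes, mitochondrial mRNAs and sensors were called lower and immediate early genes higher with camera (limma) adjusted p at most 0.0341, but at least 0.0815 with an estimated correlation. Against WT, cholesterol synthesis, unfolded protein response, mesothelial and glycolysis genes were called lower and matrix, immediate early and cell cycle genes higher, with camera (limma) adjusted p at most 0.00403, or 0.0427 with an estimated correlation. GTPases, sensors, signalling genes, class I genes and mitochondrial mRNAs were called lower there and NF-kB targets higher with camera (limma) adjusted p at most 0.0412, but at least 0.0591 with an estimated correlation.

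Clone 2CD7 differed from EV in 468 higher and 569 lower genes when untreated. Gucy2c, an intestinal guanylate cyclase receptor gene, was at least 18.9-fold higher, Sema5a at least 11.3-fold, Tmem184a at least 3.15-fold and Rab38 40.6-fold (95% counting interval 6.91 to 1640), while Wfdc1 was higher by 4.31 ± 0.54 on the log2 scale. Igsf11 was at least 9.89-fold lower, Oas1a 106-fold (95% counting interval 18.6 to 4225), Oas1g 51.2-fold (95% counting interval 17.2 to 251), Slfn2 at least 8.47-fold and Bhlhb9 at least 7.77-fold. Of these, Sema5a, Tmem184a, Rab38, Wfdc1, Igsf11, Oas1a and Oas1g had differed between EV and WT in the opposite direction, and in 2CD7 against WT none of the 7 passed the test (edgeR adjusted p at least 0.0519). Of 57 antiviral effectors 31 were lower and 1 higher (35 and 1 adjusted over the list alone), with a median of -1.36, or -1.34 with genes at 0 set at their bound. Immediate early genes were lower in 9 of 23 cases (12 adjusted over the list alone), led by Gadd45g (-1.15 ± 0.16) and Fosl1 (-0.90 ± 0.12). Matrix genes were lower in 11 of 26 cases with 2 higher (14 and 2), led by Col5a1 (-3.66 ± 0.53) and Thbs1 (-1.29 ± 0.16). Mesothelial markers were higher in 6 of 8 cases (6 adjusted over the list alone), led by Upk3b (1.83 ± 0.42). These 4 groups had camera (limma) adjusted p at most 1.50e-09, or 0.0236 with an estimated correlation. Against WT, 14 antiviral effectors were lower (27 adjusted over the list alone), with a median of -1.06, or -1.05 at the bound, and camera (limma) adjusted p = 3.00e-28, or 0.0308 with an estimated correlation. The other 3 groups differed from EV in the direction opposite to that of EV from WT, and against WT 2 immediate early genes were higher (median 0.17), 3 matrix genes lower (median -0.13), and 2 mesothelial markers higher and 1 lower (median -0.04), with camera (limma) adjusted p = 5.91e-05, 0.00141 and 0.759, or 0.0649, 0.0424 and 0.797 with an estimated correlation. GTPases (4 of 19 lower) and nucleic acid sensors (6 of 17 lower) were called with camera (limma) adjusted p = 2.69e-05 and 0.000595, but 0.149 and 0.253 with an estimated correlation, and ribosomal protein genes (2 of 38 higher and 1 lower) with 0.0357, but 0.721. Of the group members named, Gadd45g, Fosl1, Col5a1, Thbs1 and Upk3b had also differed between EV and WT in the opposite direction. Against WT, GTPases (3 of 19 lower), sensors (8 of 17) and signalling genes (4 of 28 lower and 1 higher) were called lower and cell cycle genes (2 of 44) higher with camera (limma) adjusted p at most 5.91e-05, or 0.0308 for each with an estimated correlation, while immune checkpoint ligands (2 lower) and ribosomal protein genes (1 higher) had 0.0406 and 0.00238, but 0.160 and 0.633. The largest edgeR adjusted p among the genes named here was 0.0185. Against WT, untreated 1CF10 differed in 958 higher and 1289 lower genes and untreated 2CD7 in 170 higher and 241 lower, where DESeq2 called 729 and 972 in 1CF10 and 119 and 136 in 2CD7, the last pair with 3629 genes given no adjusted p, and limma-voom 954 and 1283 and 164 and 230.

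**Figure D4:**
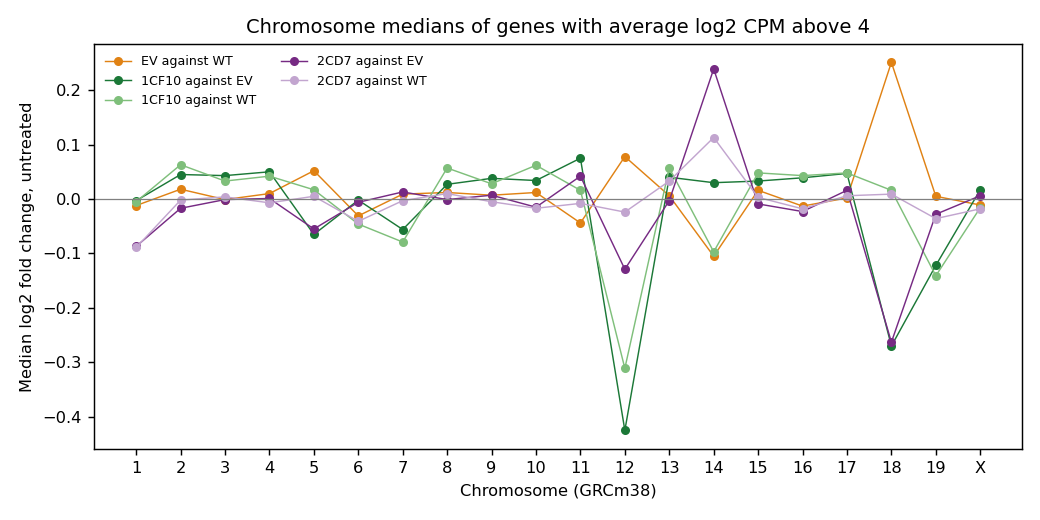
Median log2 fold change between untreated lines of the genes on each chromosome with an average log2 CPM above 4, with a point per comparison joined by lines for reading. Chromosome 12 stands at -0.43 in 1CF10 against EV and -0.31 against WT, and chromosome 18 at 0.25 in EV against WT.

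Some differences between the untreated lines followed whole chromosomes (GRCm38), a pattern looked for after the data were seen. The 229 genes of chromosome 12 with an average log2 CPM above 4 had a median log2 difference of -0.43 in 1CF10 against EV and -0.31 against WT, with 87.8% and 86.5% of them lower. The 209 genes of chromosome 18 had medians of 0.25 in EV against WT, -0.27 in 1CF10 against EV and -0.26 in 2CD7 against EV, and the 260 genes of chromosome 14 had medians of 0.24 in 2CD7 against EV and 0.11 against WT. In none of these 7 cases did any of 1000 random sets of as many genes have a median as far from 0. Smaller shifts on other chromosomes were also beyond the random sets, such as -0.14 for the 316 genes of chromosome 19 in 1CF10 against WT. Differences of 1CF10 in single genes of chromosome 12 and of EV in genes of chromosome 18 therefore include these shifts.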

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

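The tests of the 3 patterns weighed here and the counts over other splits of the samples were set down only after the results were seen, while the interaction tests were planned.

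Responses to IFN beta that differed between groups of lines by an interaction test (edgeR) were taken for a closer look. Between the clones and the controls, 430 genes had a lower and 183 a higher response in the clones. Between EV and WT, Rrm2 (0.59), Ssr1 (0.54) and Nrn1 (0.56) had a higher log2 response in EV, and 9930111J21Rik2 (-0.88) and Gm6475 (-1.43) a lower response. Over 100 splits of the samples drawn at random, with the real one included, 1 gave as many as 613 genes for clones against controls, and the highest other split gave 359. For the 5 genes of EV against WT, 4 of 50 splits gave as many, with a highest of 1350. For the 0 genes of 2CD7 against 1CF10, 50 of 50 splits gave as many, with a highest of 1262. All these splits reassign technical replicates between lines, separately within untreated and treated libraries. Groups then mix libraries of different lines, so differences between lines enter both the spread and the calls of a split. A split that exchanges lines in untreated or treated libraries alone turns differences between lines into differences of responses. The counts therefore measure neither technical spread alone nor chance between lines. Whether such splits are those that call over 1000 genes was not tested. With lines kept whole, the 4 lines can be parted in pairs in 3 ways and 2 lines in 1, too few for a share under 0.05.

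For the comparisons of 3 with 3 libraries, the 10 possible splits are too few for a share under 0.05. The real split gave 801 genes for IFN beta in WT, 596 in EV, 1649 for untreated EV against WT, 1212 for untreated 1CF10 against EV and 1037 for untreated 2CD7 against EV, each as 1 of 10 splits with as many and a highest other of 0. For IFN beta in 1CF10 the real split gave 0 genes and the highest other 13, and in 2CD7 0 and 0, with 10 of 10 splits giving as many. For the 33 genes different in both untreated clones from both controls, 1 of 100 splits gave as many, and the highest other gave 0, which decides nothing about chance between lines for the same reason.

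The first pattern was the higher level of interferon-stimulated genes in treated 2CD7 library 2, where 96 of the 123 genes raised at least 4-fold in both controls lay above the untreated mean (median log2 difference 0.44), against 61 and 56 in libraries 1 and 3 (median 0). A share of 1.53% to 1.81% of RNA or reads from treated control wells may account for the excess (chi-square p = 0.143 at the best share). The spread in that test was estimated with this library included, so the test is lenient and gives weak support. Single genes asked for unlike shares: 5.04% (Tgtp1, 74 UMIs in library 2), 0.491% (Rsad2, 25 UMIs) or -0.00785% (Isg15, 9 UMIs). These gaps were not tested gene by gene. A weak response of the whole clone stays open, since libraries 1 and 3 lay 0.003 above the untreated mean with a 95% interval from 0 to 0.104. That interval lies below the 0.44 of library 2, which argues against such a response as the whole cause of the excess. Which well the excess may have come from was not tested.

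The second pattern was the lower level of antiviral effectors in the untreated clones, with a median log2 difference of -1.14. Without untreated WT library 2 and EV library 3, which held more of these transcripts than their replicates, and treated 2CD7 library 2, the median was -0.83 (95% interval over genes -1.37 to -0.63), and with all libraries thinned to the same depth it was -1.14 (-1.81 to -0.81). Both medians stayed below 0, so by these values neither those libraries nor depth accounted for it whole. A fixed share of RNA from treated wells in the untreated control libraries was argued against as the whole cause: the 128 UMIs of Rsad2 in untreated controls allow a share of at most 0.955% (upper 95% limit), and with this share taken off, the median of the 54 effectors raised in both controls was -0.68 (95% interval -0.93 to -0.46), against -1.02 before. A smaller share stays open for part of it. Differences between lines unrelated to the Ifnar1 edit may account for it and cannot be told apart from the edit: the other ways to part the 4 lines in pairs gave medians up to 0.165, but 3 ways are too few to exclude chance. A loss of signalling from interferon that the cells make themselves is a candidate explanation that was not tested.

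The third pattern was the lower expression of chromosome 12 genes in 1CF10. It was not confined to the untreated libraries, since the treated libraries of 1CF10 and EV differed by a median of -0.38 (95% interval -0.42 to -0.32). Scaling shifts all genes of a library alike and was argued against, since chromosome 12 genes lay -0.44 (95% interval -0.48 to -0.41) from the median of the other chromosomes in untreated 1CF10 against EV. A loss of copies of chromosome 12 in this clone may account for it, as all 8 medians of 4 consecutive parts of the chromosome against EV and WT were negative, the highest being -0.29. No DNA measurement was used here.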

How the results depend on the processing

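The alternative without 3 libraries (untreated WT library 2, untreated EV library 3 and treated 2CD7 library 2) was chosen after seeing the data, and the others were planned. Over 568 named genes and contrasts, 9088 of 9972 values under the alternatives kept their direction and their side of the threshold, 877 kept the direction but not the call, 1 became a call and 6 reversed, all of Ifnar2. That value, the untreated clones minus controls, was 0.002, and it was -0.024 without the 3 libraries and between -0.077 and 0.151 with 1 library left out, all near 0 and uncalled. Where a count changed, the cause was not tested.

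With DESeq2, 119 genes fell in WT and 66 in EV, 89 had a higher response in the clones, 279 were higher in untreated 1CF10 than in EV, and 3 genes were higher in both untreated clones. Without the 3 libraries, 141 genes fell in WT, 14 genes were lower in both untreated clones, of which 13 were among the 28, and the antiviral median in 2CD7 was 0. Without a filter on low counts, 1 gene had a higher response in 2CD7 than in 1CF10. With the estimated correlation, 49 of 86 calls of gene lists held, and in the clones against WT, counted apart, 7 of 14 in 1CF10 and 7 of 12 in 2CD7.

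The response of EV against WT, with 3 higher and 2 lower genes, depended most on the settings. The higher genes numbered 0 with DESeq2 and with thinned libraries, 1 with limma-voom and the stricter filter, 51 without a filter, 8 with the replicate block, 10 without the 3 libraries and 20 with the groups of the comparison alone. The lower genes numbered 1 with DESeq2 and limma-voom, 25 without a filter, 6 with the block, 4 with thinned libraries, 14 without the 3 libraries and 10 with the groups alone. No other count moved by more than 1.5 times with the replicate block.

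Leaving out 1 library at a time, the falling genes ranged from 120 to 160 in WT, 75 to 113 in EV and 0 to 1 in 2CD7, the higher responses in the clones from 122 to 187, and the EV against WT responses from 0 to 12 higher and 0 to 21 lower. Genes lower in untreated EV than in WT ranged from 551 to 708, genes common to both clones from 3 to 6 higher and 13 to 32 lower, and the antiviral median in 2CD7 from 0 to 0.40, being 0 without treated library 2. Thinning to 1972192 UMIs moved no count by more than 1.5 times other than those of EV against WT, and in simulated 1CF10 data, at the sizes of the libraries before thinning, 50% of the 1.5-fold changes were called.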

Other observations

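The tests reported here were chosen after the results were seen. Of the genes lower in both untreated clones, Ggh (GRCm38 chromosome 4, 20042052 to 20066750) and Cacna2d2 (chromosome 9, 107399612 to 107529343) did not rise with IFN beta. They were not the only exceptions: Ifi27l2a, Ifi27, Spp1, Scd1, Nrn1, Clu, Capg and Laptm4a were not called as raised in both controls either. Rassf1 (chromosome 9, 107551555 to 107562267), which lies beside Cacna2d2, was higher in both clones, by 0.44, 0.67, 0.30 and 0.53 on the log2 scale. No explanation was tested for these genes.

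Between replicates of a group, the chi-square per gene ran from 1.40 to 2.70 over all pairs of libraries, apart from the pairs with treated 1CF10 library 3, at 4.74 and 3.68. The 123 genes raised at least 4-fold in both controls summed to 666 to 1267 CPM in untreated WT and 818 to 1145 CPM in untreated EV, with the highest in WT library 2 and EV library 3, against 460.3 to 551 CPM in the untreated clones. Chromosome 18 genes stood at a median log2 difference of 0.02 in 1CF10 and 0.01 in 2CD7 against WT, where EV stood at 0.25, and chromosome 14 genes were 0.11 to 0.24 higher in 2CD7 than in both controls. These chromosome medians were not tested against an explanation.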
